A study of Homo sapiens with 2 samples.

How the data were processed

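The data are 2 Affymetrix arrays of the human U133A 2.0 type, 1 for gamma delta T cells treated with PBS and 1 for cells treated with LPS, each hybridised with RNA pooled from 4 individuals. Per the series' design text, RNA was extracted with TRIzol, pooled, turned into biotin-labelled cRNA with a single amplification cycle, and the scans were collected with GCOS version 1.1. The LPS preparation is called phLPS in the series' design text, which does not spell out the abbreviation. The deposited values are probe set signals on a linear scale, from 0.20 to 102572, without detection calls. The algorithm that made them and its settings are not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets was 500.2 on both arrays, so by these values the deposited signal had been scaled to a common level, and it was not on a log scale.

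From the deposited signals, the 62 control probe sets were set aside and each array was scaled to a common mean, leaving out the lowest and highest 2% of the 22215 remaining probe sets. The scale factors were 1.00 on both arrays. Because dim probe sets vary most, a floor was set at the median of all signals, 126.1, which 49.8% of PBS and 50.2% of LPS probe sets reached. Signals under the floor were raised to it before the log2 ratio of LPS over PBS was taken. A fold with 1 side under the floor is a lower bound and is written as at least that fold. A floor hides differences among dim genes and narrows the folds of those near it.

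Gene names came from the platform's annotation, updated through gene identifiers to the GRCh38.p14 RefSeq gene table, in which 19052 of the 19064 probe sets with 1 gene symbol were found. Of the other probe sets, 1043 carried several symbols and 2108 were not listed, and these are unnamed here. CCL3 and CSF2 had no probe set of their own in that annotation and were not analysed here as named genes. Each of the 11963 genes was represented by its probe set with the highest mean signal. Leaving out 24 sex-linked genes, 7169 genes were at or above the floor on at least 1 array. Probe sets are probes near the 3' end of transcripts and some, including those with IDs ending in _s_at or _x_at, can bind transcripts of related genes: 40 of the 86 higher and 26 of the 55 lower genes rest on such probe sets.

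With 1 array per group, no test, p-value or error between cultures can be had. Genes were therefore counted at a fixed size of change, 2-fold. For 29 gene lists, the median log2 ratio of the members at or above the floor was placed among 10000 random lists of the same size, drawn from genes in the same of 20 signal bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5, and 5 measured members were required, which 26 lists had. The percentile describes these 2 arrays and is not a p-value, since genes are not replicates. With 26 lists, 1.3 would stand apart on average if the lists were random. Members of 1 list may vary together, so that this figure may be too low for such lists. Lists share some members. The size of change, the floor, these 29 lists, the rule for named genes and all alternatives for these results but 1 were fixed before the data were examined, whereas 3 further lists, given at the end with their alternatives, were chosen later. That rule names the 15 genes with the highest and the 15 with the lowest ratio, up to 4 members with the largest ratios of each list that stood apart or held a member past 2-fold, and 16 genes of LPS sensing and response whatever their values.

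The arrays were compared on their control probe sets. The 18 bacterial and phage hybridisation controls above the floor had a median log2 ratio of -0.16 with an SD of 0.15. The 3' over 5' signal ratio was 18.6 with PBS and 19.4 with LPS for ACTB, and 14.9 and 13.1 for GAPDH, so both arrays carried strongly 3'-weighted targets. The median log2 ratio of all genes was -0.03. Measurement error was estimated from the difference in log2 ratio between the 2 brightest probe sets of the same gene, which holds probe and hybridisation noise but not the spread between cultures or donors.

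The steps were tested on simulated data over 7018 genes, made from the mean of both arrays with this noise, with changes planted in genes whose PBS signal was over 2 times the floor. Of 50 genes changed 4-fold, 100% passed the 2-fold size, against 94% of 50 changed 3-fold, 48% of 50 changed 2-fold and 4% of 50 changed 1.5-fold. Of 6798 unchanged genes, 17 passed it. The simulated noise came from probe sets at or above the floor on both arrays, and dimmer probe sets were given that of the dimmest of these. The count of 17 may therefore be too low for genes with 1 signal under the floor. A planted list of 20 genes changed 1.4-fold stood at percentile 100, and 3 of 100 unchanged lists stood apart. The simulated noise was independent between probe sets, and the unchanged lists were drawn at random. The 3 of 100 therefore do not show how often lists of genes that vary together would stand apart without an effect of LPS. Alternatives were other scalings (values as deposited, median scaling, quantile normalization, lowess), other floors (none, the 40th and the 60th percentile, the median signal as a pseudocount), other choices of probe set, sizes of 1.5-fold and 3-fold, and other matching of the random lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.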

Results

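Gene expression was measured in human gamma delta T cells, a class of T lymphocytes whose antigen receptor is built from gamma and delta chains. The cells had been expanded in culture, sorted and exposed for 4 h either to phosphate-buffered saline (PBS, the control) or to lipopolysaccharide (LPS, an outer membrane component of Gram-negative bacteria that is sensed through Toll-like receptor 4). RNA from 4 individuals was pooled for each treatment and hybridised to 1 oligonucleotide array, so the data consist of 1 PBS array and 1 LPS array. Both arrays reported 22277 probe sets. Their signals correlated with a Spearman coefficient of 0.918 across the 22215 non-control probe sets, which are not independent replicates. Each difference below is between 2 pooled samples and has no replicate check, so no p-value or error is attached to it. Error within the data was measured by the disagreement between probe sets of the same gene, which had an SD of 0.32 on the log2 scale over 1915 genes. With the genes parted by signal into 4 equal groups, that SD was 0.40 in the dimmest and 0.22 in the brightest group. The log2 ratios of the 2 probe sets had the same sign in 56.4% of the 1915 genes. Their Pearson correlation across genes was 0.21, so a modest ratio of a single gene is uncertain.

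The comparison of LPS with PBS asked which transcripts of gamma delta T cells differ after a short exposure to a bacterial product. The 15 genes with the highest ratios included 5 transcription factor genes of early lymphocyte activation, the cytokine gene TNF and the chemokine gene XCL1. The transcription factor EGR3 had a signal of 134.7 with PBS and 2057 with LPS, which is 15.3-fold higher, and ranked first among the 7169 genes at or above the signal floor of 126.1 once dimmer signals were raised to that floor. Ratios raised in this way are lower bounds, so that NR4A3 and SGK1 cannot be ranked against EGR3. The orphan nuclear receptor NR4A3 was at least 13.1-fold higher, its PBS signal of 93.0 lying under the floor. That bound depended on the setting, and the log2 ratio of NR4A3 was 1.24 with the mean of all probe sets, which counts 2 probe sets under the floor on both arrays, against 3.71. Its relative NR4A2 was 9.99-fold higher, from 182.7 to 1826. With the median signal added as a pseudocount, the log2 ratios of EGR3 and NR4A2 were 3.07 and 2.66, against 3.93 and 3.32. TNF, the inflammatory cytokine, was 5.14-fold higher, from 850.9 to 4370. XCL1, a chemokine made by lymphocytes, was 4.31-fold higher, from 3754 to 16169, although its probe sets can also bind the near-identical XCL2. CCL4, a chemokine that attracts monocytes and T cells, was 3.07-fold higher, from 14036 to 43056.

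In all, 86 genes were at least 2-fold higher and 55 at least 2-fold lower with LPS, together 1.97% of the genes compared. At a size of 3-fold with the floor applied, 21 genes were higher and 0 were lower, and 11 were at least 4-fold higher. The genes higher with LPS were also the brighter ones, with a median signal of 596.0 on their brighter array against 327.1 for the genes lower with LPS. The PBS signal of 19 of the 86 and the LPS signal of 19 of the 55 lay under the floor, so that their folds are lower bounds. Of the 86 higher genes, 22 had a further probe set at or above the floor. The ratio of that probe set was also above 1 in 17 of them, at least 1.5-fold higher in 12 and at least 2-fold higher in 6. Of the 55 lower genes, 8 had such a probe set, and it was also lower in 4 of them and at least 1.5-fold lower in 0. Both counts depended on the floor: with the floor at the 60th percentile of all signals they were 51 higher and 13 lower. Among the named genes past 2-fold, 10 of 29 higher and all 18 lower genes fell under 2-fold with at least 1 alternative.

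**Figure D1:**
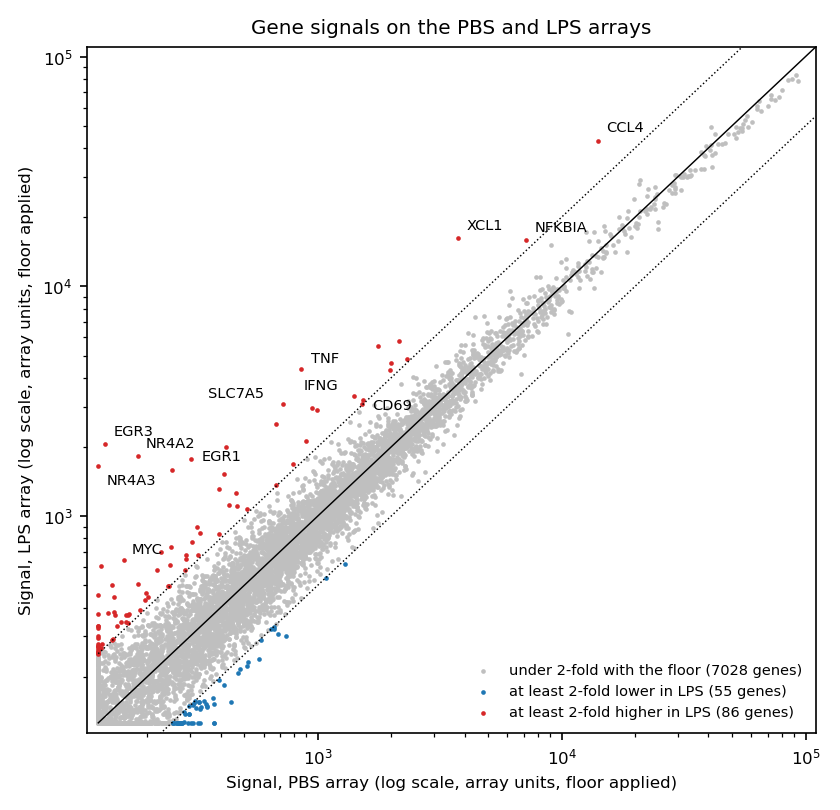
Signal of each of the 7169 genes on the PBS array (horizontal, log scale) and on the LPS array (vertical, log scale), with values under the floor raised to it; the solid line marks equal signals and the dotted lines 2-fold differences. The 86 genes at least 2-fold higher with LPS reach 15.3-fold, whereas with the floor applied none of the 55 lower genes reaches 3-fold, and 19 of them lie at the floor on the LPS array.

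Genes of early T cell activation were higher together. Of the 27 measured members of the list of activation and immediate early genes, 10 were at least 2-fold higher with LPS and 0 at least 2-fold lower. Another 15 lay within 2-fold, and 2 had 1 signal under the floor and only a lower bound under 2-fold. The median log2 ratio was 0.81, above all 10000 random lists of equal size and signal. Besides EGR3, NR4A3 and NR4A2, the zinc finger factor EGR1 was 5.86-fold higher, from 303.2 to 1776, and MYC, a driver of cell growth, was 4.01-fold higher, from 160.3 to 642.8. CD69, an early surface marker of lymphocyte activation, was 2.02-fold higher, from 1519 to 3072. Not all members were higher: JUN had a log2 ratio of 0.07, SLAMF1 -0.17 and DUSP1 -0.37, chosen after their values were seen. The further probe sets of NR4A2 had log2 ratios of 2.84 to 3.52 and that of EGR1 had 1.63, against 3.32 and 2.55 for the probe sets used.

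Targets of NF-kappaB, the transcription factor downstream of Toll-like, antigen and TNF receptors, showed a similar difference. Of 23 measured members, 7 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.69, above all 10000 random lists. The stress-response gene IER3 was 3.75-fold higher, from 672.3 to 2520. TNFRSF9, the costimulatory receptor 4-1BB, was 3.71-fold higher by its brightest probe set, whereas another probe set of the gene gave a log2 ratio of only 0.15. The survival gene BCL2A1 was 2.58-fold higher. Among inhibitors of NF-kappaB, NFKBIA was 2.22-fold higher, from 7133 to 15851, and NFKBIE was 2.34-fold higher. TNFAIP3, an enzyme that dampens NF-kappaB signalling, was already bright with PBS at 12579 and reached 17175 with LPS, a 1.37-fold difference. IRF1 was lower, with a log2 ratio of -0.31, and CFLAR had 0.15, both chosen after their values were seen.

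Chemokines and cytokines differed by gene. Of 24 chemokines represented, 6 were at or above the floor, 3 of which were at least 2-fold higher and 0 at least 2-fold lower. Of the rest, 1 lay within 2-fold and 2 had only a lower bound under 2-fold. The median log2 ratio of the 6 was 0.90, above all 10000 random lists. CCL1, a chemokine of activated T cells, was 2.51-fold higher, from 306.2 to 768.3. CXCL8, the neutrophil attractant interleukin-8, was dim on both arrays, at 53.2 with PBS and 174.6 with LPS, and at least 1.38-fold higher. CCL5 had one of the brightest signals on both arrays, at 79935 with PBS and 71546 with LPS, a log2 ratio of -0.16; it was chosen after its values were seen.

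Of 8 measured T cell effector cytokines, 3 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.61 that lay above all 10000 random lists. IFNG, the macrophage-activating cytokine interferon gamma, was 2.36-fold higher, from 1410 to 3331, and LTA, or lymphotoxin alpha, was at least 2.63-fold higher, from 96.4 to 331.9. FASLG, the death ligand of cytotoxic cells, was 1.57-fold higher, a log2 ratio of 0.65, with 0.36 from another probe set. Of 11 measured inflammatory cytokines, 2 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.42 at percentile 99.9 of the random lists. The 2 were TNF, which is a member of both cytokine lists, and TNFSF14, a costimulatory ligand that was 2.36-fold higher. IL15 was 1.63-fold higher and IL1B had a log2 ratio of 0.48, whereas IL1A was 1.58-fold lower. IL6 lay under the floor on both arrays, at 42.9 with PBS and 66.2 with LPS. With a floor at the 40th percentile the median log2 ratio of inflammatory cytokines was 0.047, at percentile 74.7, so that this list did not stand apart at that setting.

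**Figure D2:**
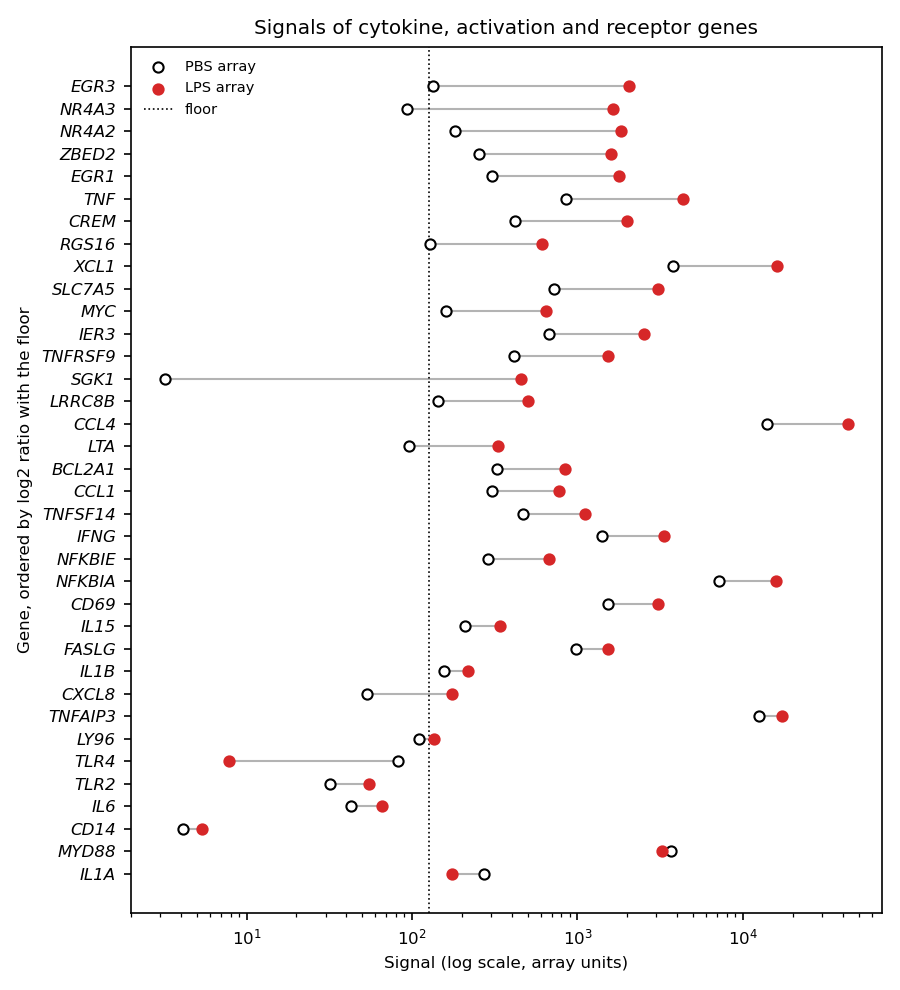
Signals (log scale, array units) of the 15 genes with the highest ratios, of the named cytokine, chemokine and NF-kappaB genes, and of the genes named whatever their values, with open circles for the PBS array, filled circles for the LPS array and a dotted line at the floor. CCL4 and XCL1 were bright with PBS and higher with LPS, whereas TLR4, TLR2, CD14 and IL6 lay under the floor on both arrays.

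The receptors for LPS were dim in these cells. TLR4, the LPS receptor, had a signal of 81.9 with PBS and 7.80 with LPS, and its co-receptor CD14 had 4.1 and 5.4, all under the floor. TLR2 was also under the floor, at 31.8 and 54.8. LY96, the TLR4 partner protein MD-2, lay near the floor at 109.6 and 135.8. MYD88, the adaptor of most Toll-like receptors, was well above it, at 3688 with PBS and 3247 with LPS. Of 13 measured components of the Toll-like receptor pathway, 10 were within 2-fold and 3 had only a lower bound under 2-fold, and the median log2 ratio of 0.06 stood at percentile 82.8 of the random lists, while the mean had the other sign, -0.03. A signal under the floor does not show that a transcript is absent.

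Interferon-stimulated genes, antiviral genes induced by type I interferon, were not higher as a list. Of 33 measured members, 0 were at least 2-fold higher and 2 were at least 2-fold lower, with a median log2 ratio of -0.11 at percentile 10.2. LY6E was 2.06-fold lower, from 663.2 to 321.5, RSAD2 was 2.01-fold lower and MX2 1.51-fold lower, whereas the guanylate-binding protein gene GBP2 was 1.58-fold higher. When all probe sets of each gene were averaged, the median was -0.17, at percentile 0.30, so that the list stood below the random lists at that setting.

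Of the other lists, 3 stood apart from random lists. The negative feedback regulators of cytokine and Toll-like receptor signalling had a median log2 ratio of 0.29 and a mean of 0.16 over 13 genes, at percentile 99.97, with NFKBIA the 1 member past 2-fold. That list lost its standing under 2 of 12 alternatives, with percentiles down to 86.8. ZFP36, which destabilises cytokine messenger RNA, was 1.35-fold higher, and TNIP1, a partner of TNFAIP3, was 1.30-fold higher. NFKBIA, TNFAIP3 and TNIP1 are also members of the NF-kappaB list. Lower members included DUSP1, CISH and ATF3, with log2 ratios of -0.37, -0.30 and -0.27, chosen after their values were seen. The heat shock and stress genes had a median of 0.16 over 18 genes, at percentile 99.6, with 17 members within 2-fold and 1 with only a lower bound under 2-fold. GADD45A was 1.59-fold and the chaperone HSP90AB1 1.43-fold higher. HSPH1 was 1.57-fold higher by its brightest probe set, and another of its probe sets had a log2 ratio of the other sign, -0.23. The cell cycle genes had a median of -0.18 over 35 genes, at percentile 1.59, with 1 member at least 2-fold higher and 1 at least 2-fold lower. The mitotic kinase gene AURKB was 2.16-fold lower, from 297.0 to 137.3, and the centromere histone gene CENPA was 2.03-fold higher, from 144.4 to 293.5. AURKB fell under 2-fold with 2 of 10 alternatives and CENPA with 2 of 9. PTTG1 was 1.63-fold higher, and CCNE1 was at least 1.70-fold lower. The cell cycle list no longer stood apart under 7 of 12 alternatives, with percentiles up to 13.8, so that its lower median depended on the processing.

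Other functional lists lay within the range of random lists at the main setting. Cytotoxic effector genes had a median log2 ratio of -0.03 and a mean of 0.08 over 16 genes, at percentile 62.3. The sign of the median changed with all 3 other scalings that moved the ratios. Cytokine receptors had a median of -0.05 and a mean of 0.07, at percentile 39.97, although TNFRSF1B, a TNF receptor, was 2.08-fold higher. IL2RA, a subunit of the interleukin-2 receptor, was 1.75-fold higher, a log2 ratio of 0.81 that was 0.05 with the floor at the 60th percentile. IL12RB2 was 1.72-fold and IL4R 1.49-fold higher. NK receptors had a median of 0.12, at percentile 95.8. CD160 had a log2 ratio of 1.32, from 148.3 to 371.5, KIR2DL4 was 1.69-fold and NCR2 1.34-fold higher, and KLRB1 was 1.31-fold lower. CD160 fell under 2-fold with 2 of 10 alternatives, with log2 ratios down to 0.74. KIR genes are near-identical copies that probe sets can confuse, and 2 further probe sets of KIR2DL4 gave log2 ratios of 0.20 and 0.38. Unfolded protein response genes had a median of 0.11, at percentile 96.2. In that list the chaperone cofactor gene DNAJC3 was at least 2.09-fold, HSPA5 1.43-fold and ASNS 1.32-fold higher, and TRIB3 was 1.34-fold lower. DNAJC3 fell under 2-fold with 2 of 9 alternatives, with log2 ratios down to 0.24, against 1.06. Glycolysis genes had a median of 0.09, at percentile 97.3, and stood above the random lists under 2 of 12 alternatives, with percentiles up to 97.85. The hexokinase gene HK2 was at least 2.35-fold, and ALDOA 1.42-fold higher, PKM had a log2 ratio of 0.49, and ENO2 was 1.78-fold lower. Another probe set of ALDOA and of PKM gave log2 ratios of only 0.22 and 0.13. HK2 fell under 2-fold with 2 of 10 alternatives, with log2 ratios down to 0.41, against 1.23. Cholesterol and isoprenoid synthesis genes had a median of -0.20, at percentile 3.68, and stood below the random lists under 1 of 12 alternatives, at percentile 1.03. Chemokine receptors and homing molecules had -0.08, at percentile 22.4, apoptosis regulators 0.02, at percentile 71.5, metallothioneins -0.12, at percentile 18.4, oxidative phosphorylation genes -0.04, at percentile 42.6, and ribosomal proteins -0.08, at percentile 13.9.

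**Figure D3:**
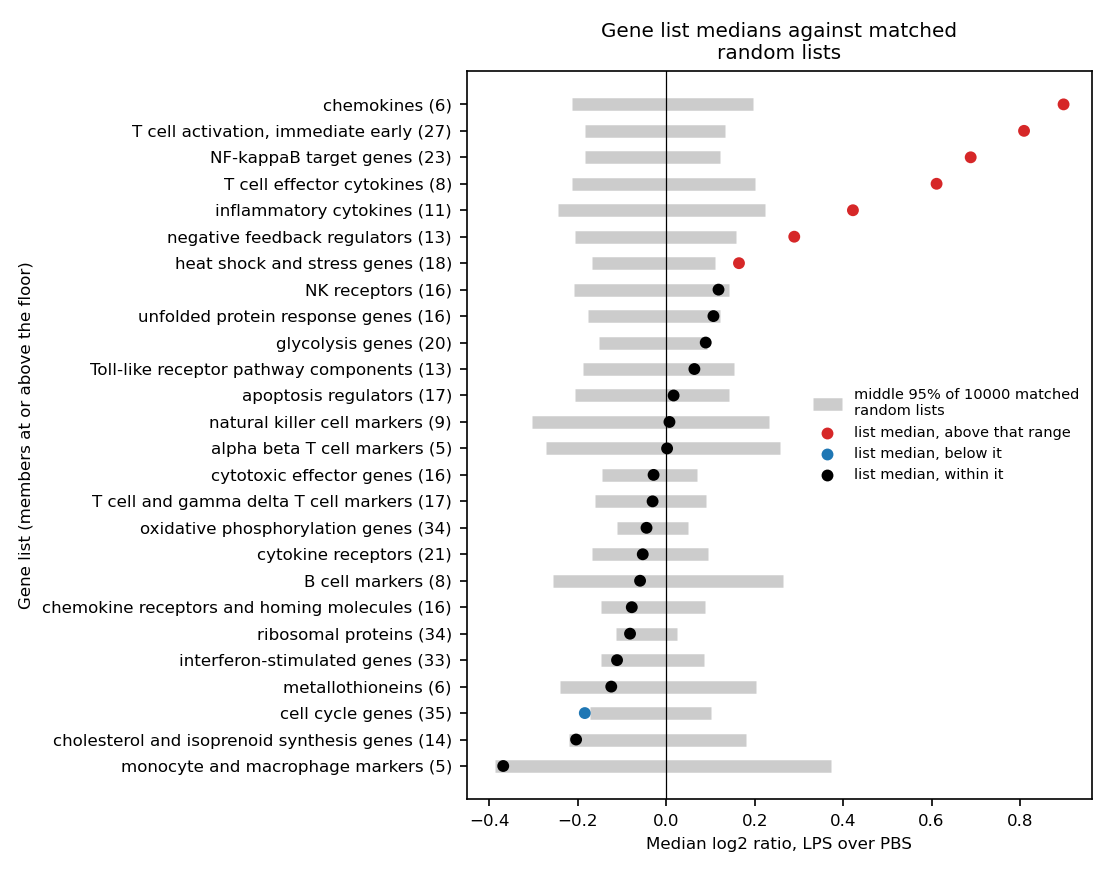
Median log2 ratio of LPS over PBS for each gene list with at least 5 measured members (points; number of members in parentheses) and the middle 95% of the medians of 10000 random lists matched on size and signal (grey bars). Chemokines, activation genes, NF-kappaB targets, both cytokine lists, feedback regulators and stress genes lie above the grey bars, and cell cycle genes lie below.

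Of 51 measured cell type markers, 38 were within 2-fold between the arrays, and 13 had 1 signal under the floor and only a lower bound under 2-fold. The 17 markers of T cells and gamma delta T cells had a median log2 ratio of -0.03 at percentile 58.2. The 2 measured members from the gamma and delta receptor loci were lower with LPS: TRDV3 had a signal of 24856 with PBS and 17764 with LPS, a log2 ratio of -0.48, and TARP had 371.3 and 192.7, a log2 ratio of -0.95. The CD3 delta chain gene CD3D had 34054 and 30364. TRDV3, TARP and CD3D were chosen after their values were seen. The list's other members from the gamma and delta receptor loci, TRDC, TRGC1, TRGC2, TRGV9 and TRDV2, had no probe set of their own. The ratios of TRDV3 and TARP therefore do not show how the receptor transcripts differed as a whole. The median of the 17 markers was 0.01 with scaling on the median above the floor. Natural killer cell markers had a median of 0.01 and a mean of -0.01 over 9 genes, at percentile 65.8, and alpha beta T cell markers 0.00 over 5, at percentile 58.3. Among the latter, TRBC1 was bright on both arrays, at 16961 with PBS and 15789 with LPS. CD8A had 1643 and 1645, whereas CD4 had 42.7 and 133.6. These were also chosen after their values were seen, and which cells the signals came from was not tested. Of 19 monocyte and macrophage markers represented, 5 were at or above the floor, with a median of -0.37 at percentile 3.72, and the list stood below the random lists under 1 of 10 alternatives, at percentile 2.15. B cell markers had a median of -0.06 over 8 genes, at percentile 31.4. Of the neutrophil, platelet and erythroid, and dendritic cell markers, 3, 3 and 1 were at or above the floor, with medians of -0.76, 0.05 and 0.63 and no percentile.

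The remaining genes with the highest ratios were not members of these lists. ZBED2, a zinc finger factor, was 6.28-fold higher, from 252.9 to 1589. CREM, a cyclic AMP-responsive transcription factor, was 4.76-fold higher by its brightest probe set, while 2 others gave log2 ratios of 0.68 and 0.81. RGS16, a regulator of G protein signalling, was 4.73-fold higher, with a log2 ratio of 0.71 from another probe set, and the amino acid transporter SLC7A5 was 4.25-fold higher, from 723.1 to 3071. The kinase gene SGK1 had a signal of 3.20 with PBS and 452.7 with LPS, and was at least 3.59-fold higher. The log2 ratio of SGK1 was 1.20 with lowess and 1.03 with the floor at the 60th percentile, against 1.84. LRRC8B, a volume-regulated channel subunit, was 3.48-fold higher, a log2 ratio of 1.80 that fell to 0.90 with 1 of 10 alternatives.

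The 15 genes with the lowest ratios had signals between 294.8 and 745.0 with PBS. MMP14, a membrane-bound matrix metalloproteinase, was at least 2.99-fold lower, TTC9 at least 2.97-fold and the non-coding gene CEBPA-DT 2.82-fold lower. EGLN3, an oxygen-sensing hydroxylase, was at least 2.61-fold lower, ERN2 at least 2.56-fold, PSRC1 2.48-fold, LDB1 2.47-fold, TPM1 at least 2.45-fold and TESK2 at least 2.40-fold lower. POLD4, a DNA polymerase delta subunit, was 2.39-fold lower, RNF122 2.38-fold, RECQL5 2.36-fold, ATRN at least 2.34-fold, GAS7 2.29-fold and MCM9 2.29-fold lower. Another probe set of ATRN, GAS7 and MCM9 had a ratio of the other sign, with log2 ratios of 0.12, 0.12 and 0.14. Further probe sets of LDB1 and TPM1 were lower by less, with log2 ratios of -0.39 and -0.38.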

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

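The tests of RNA integrity, array scaling, monocytes and other differences between the pools were chosen only after the results were seen. Outside the named genes, 17 probe sets that the annotation pairs with several genes or with none were at least 2-fold higher with LPS, in data that the comparisons above do not use, and 17 were at least 2-fold lower. The highest ratio among them came from a probe set the annotation does not list, with signals of 904 with PBS and 6500 with LPS. Another unlisted probe set had 716 and 3133, and one shared by 3 genes had 8543 and 20209.

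The genes higher and lower with LPS differed in how their further probe sets behaved. Noise of single probe sets would leave the next brightest probe set near a ratio of 1. For the higher genes its median log2 ratio was 0.683 over 22 genes, which argues against noise as the source of the whole group. For the lower genes it was 0.018 over 8 genes, as such noise would leave it. In the simulation, however, noise took only 17 of 6798 unchanged genes past 2-fold in both directions together. Of the 55 lower genes, 36 were at or above the floor on both arrays, more than the simulated noise accounts for. Either that noise was too small or the lower genes are not noise alone, and these values cannot tell which. Poorer RNA on the LPS array is argued against by the 3' over 5' ratios, the smaller of whose log2 changes was -0.185. The 3' over 5' ratios only compare the arrays with each other, and both arrays carried strongly 3'-weighted targets. A true loss of some transcripts stays open, since only 8 of the 55 lower genes had a further probe set.

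The activation genes were higher together in a single pool. The lowest median of the activation list over the 3 other scalings that moved the ratios was 0.83. Each of these scalings keeps the bulk of genes near a ratio of 1, so this could hardly have come out otherwise. It shows only that the list's median did not depend on the choice among these scalings. Monocytes in the LPS pool, which respond strongly to LPS and which sorting should remove, are argued against: 0 of the abundant monocyte genes LYZ, S100A8, S100A9 and CD14 reached the floor on the LPS array, with signals of 8.1, 7.7, 35.8 and 5.4. A difference between the pools other than LPS, such as handling, cannot be told apart from the treatment, because there is 1 array per group. An effect of LPS itself stays open beside it.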

How the results depend on the processing

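The setting that required both arrays to reach the floor and the alternatives of the 3 later lists were tests chosen only after the results were seen. Scaling left the counts within 1.5 times, from 86 to 91 higher and from 44 to 61 lower genes, against 86 and 55. The floor moved them most: 1535 higher and 1260 lower with no floor, 182 and 145 at the 40th percentile, and 51 and 13 at the 60th. At 1.5-fold the counts were 378 and 366, and at 3-fold 21 and 0. The lower count was 31 with the median signal as a pseudocount and 34 with the mean of all probe sets, where the higher counts of 68 and 65 stayed within 1.5 times. Without _s_at and _x_at probe sets, which leaves 4408 genes, the counts were 54 and 31. With genes at or above the floor on both arrays the lower count was 36. At the 60th percentile all 51 higher and 13 lower genes were among the 86 and 55, which holds by construction, since a higher floor can only narrow a ratio. With the pseudocount 47 of 68 higher and 10 of 31 lower genes were among them. The activation, NF-kappaB, chemokine and T cell effector cytokine lists stood above the random lists under every alternative run, with medians of 0.50 to 0.89, 0.40 to 0.77, 0.78 to 1.37 and 0.51 to 0.65. The inflammatory cytokine median was 0.047 with the floor at the 40th percentile and 0.16 with the mean of all probe sets, and at both the list no longer stood apart. The interferon-stimulated median was -0.17 with the mean of all probe sets, where the list stood below the random lists. The cell cycle list lost its standing under 7 of 12 alternatives. Over the 26 fixed lists with a percentile, 288 of 304 alternative values kept their side of the limits, and 0 reversed. Over the 3 later lists, all 35 kept theirs. Of 738 alternative values of named genes, 642 moved by less than the probe set SD, 96 by more, and no gene past 2-fold changed sign. That was largely fixed in advance: a floor or a pseudocount cannot reverse a ratio, and the deposited values nearly equal the scaled ones. The absence of sign changes therefore bears mainly on the other scalings and the choice of probe set. The 642 include the values as deposited, which could hardly move. Calls of named genes past 2-fold did end: 10 of 29 higher and all 18 lower genes fell under 2-fold with at least 1 alternative. With the floor at the 60th percentile 5 higher and 14 lower genes did, with the pseudocount 5 and 13, with the mean of all probe sets 3 and 8, and with lowess 0 and 2. No call could end without a floor or with it at the 40th percentile, since a lower floor can only widen a ratio. The disagreement between probe sets kept within 1.5 times with the floor at the 60th percentile. No alternative could leave out a replicate, because each group has 1 array. Signals near the floor limit the folds of dim genes. Where a value moved, the cause was not tested beyond the construction of the alternative.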

Other observations

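The 3 gene lists of this part were chosen after the highest-ranking genes had been seen and before the values of their own members were, while the tests of the lists under other settings were chosen only after their main results were seen. The list of ribosome biogenesis genes, which act in assembling ribosomes in the nucleolus, had a median above those of random lists. Of 20 measured members, 2 were at least 2-fold higher, 0 at least 2-fold lower, 16 within 2-fold and 2 had only a lower bound under 2-fold, with a median log2 ratio of 0.32. The processing factor genes UTP20 and NIP7 had log2 ratios of 1.15 and 1.03, the helicase gene DDX21 had 0.79, the nucleolar phosphoprotein gene NOLC1 had 0.49, and NPM1, bright on both arrays, had 0.16. RRP9 and GRWD1 were lower, with -0.32 and -0.07. Ribosomal proteins themselves had a median of -0.08.

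MYC, whose known targets include ribosome biogenesis genes, was 4.01-fold higher, and a hypothesis that these genes were higher together was tested: the list stood at percentile 99.96 of matched random lists, consistent with it, and between 99.4 and 100 over 12 alternatives, although 2 arrays cannot show that MYC is the cause. A second hypothesis, that amino acid transporters other than SLC7A5 were higher together, was left open, the list of 10 genes having a median log2 ratio of 0.11 at percentile 86.8. A further hypothesis, that genes of T cell quiescence were lower, was also left open, with a median of -0.13 over 11 genes at percentile 11.2. In that list TOB1, an inhibitor of proliferation, had a log2 ratio of -0.64 and KLF2 had -0.06.

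Among chemokine receptors, CCR2 had a signal of 6842 with PBS and 4174 with LPS, a log2 ratio of -0.71, and CX3CR1 had 8530 and 7678. The granzyme gene GZMB had 20944 and 28997, and the perforin gene PRF1 37288 and 32540. CRTAM, a surface molecule of activated cytotoxic lymphocytes, had 2148 and 5760. These genes were chosen after their values were seen.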
